A study of Homo sapiens with 12 samples.

How the data were processed

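PolyA RNA was sequenced in 12 libraries from 3 established human kidney lines, CAKI-1, A704 and HK2. Each line was transfected with a non-targeting control siRNA, a LATS siRNA and each of 2 independent PTPN14 siRNAs at 25 nM, using a lipid reagent, and RNA was taken at 48 h. Each reagent gave 1 library per line, so the groups held 3 control, 3 LATS and 6 PTPN14 libraries. The labels do not say that these came from separate cultures, so p-values measure the spread between these libraries, across lines and siRNAs. The labels give an RNA integrity number of 10 for every library except the A704 control, at 9.6. The sample titles and descriptions number the PTPN14 siRNAs the opposite way round in all 3 lines; the title numbers are used here. The labels do not say whether the LATS siRNA was aimed at LATS1, LATS2 or both.

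The authors deposited 1 table of FPKM values per gene symbol, rounded to 2 decimals. The unit was taken from the values, which are not whole, sum to between 344334 and 396360 per library and fall in proportion to gene length at their lowest step. Reads were aligned with STAR 2.4.0g1 to GRCh38.p1 per the submitters' processing notes. The library kit marks strand, per the labels. The gene counter, its annotation, its strand setting and the scaling of the libraries are not given in the sources used here. The table holds 20979 entries with 19156 distinct symbols, of which 695 stand on more than 1 line. A further limit is that 29 entries carry dates in place of gene symbols, and these are named nowhere.

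FPKM values are not counts, so depth was sought in the low values. The lowest values of 43 to 76 single-exon genes per library lay on whole-read steps. At the best step, 85.7 to 96.3% of these genes lay within the rounding of the file, against a median of 9.8 to 14.3% at other step sizes. The effective depth this gives ran from 17.0 M reads (HK2 with PTPN14-1) to 23.3 M reads (CAKI-1 with LATS siRNA). It is an estimate, since the authors' gene lengths are not given.

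Values were tested as log2(FPKM + 1), so changes are on that scale and understate those of low genes. The 12276 genes above FPKM 1 in at least 3 libraries were kept; 2 of their symbols stand on more than 1 line. Linear models were fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation (statmod 1.5.0), and p-values were adjusted by Benjamini-Hochberg at 0.05. The planned test assumed counts, and its stated fallback for normalised values was used. The target model had cell line as a block and siRNA target (control, LATS, PTPN14), which leaves 7 residual degrees of freedom. The reagent model replaced target by the 4 reagents, with 6 degrees of freedom, and served to compare the PTPN14 siRNAs with each other and each with control. Changes within a line and the line-by-target interaction came from a model of the 9 line and target groups, whose 3 degrees of freedom all come from the PTPN14 pairs. Libraries of 1 line pair across siRNAs because they are the same cell line; in a principal component analysis of the same values the first 2 components, with 57.0 and 38.1% of the variance, separated the lines.

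Gene lists written before the data were examined cover Hippo signalling, cell cycle, stress, metabolism, adhesion, signalling feedback, kidney segments and other cell types; 29 of them had at least 3 measured members. They were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, for 1 direction and, where stated, for mixed directions. Adjustment ran over 87 tests for the PTPN14, LATS and difference contrasts, and over 87 further tests for each PTPN14 siRNA and their difference. The design, lists, thresholds and the rule for naming genes were all set before the data were examined; the list tests by single PTPN14 siRNA and the tests named below as later were not. The naming rule takes the siRNA targets with YAP1 and WWTR1, and up to 10 genes with the largest rise and the largest fall past the threshold, with a mean FPKM over 1 and 1 direction in all lines and siRNAs. It also takes up to 4 members per list with the smallest p, and the 10 smallest p for the interaction and for the difference between the PTPN14 siRNAs. The rule was applied to each PTPN14 siRNA alone, and examples were taken from the genes shared by both, after the values were seen. Other genes outside it are named as such.

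On simulated data with 200 changed genes in each of 10 sets of 12276 genes, the PTPN14 contrast recovered 28.2% of 1.25-fold changes, 90% of 1.5-fold and 99.2% of 2-fold. The LATS contrast recovered 14.4, 77.8 and 98%, and the contrast between PTPN14 siRNAs 33.6, 95 and 99.4%. False calls made up 5.14, 6.22 and 5.58% of all calls. These sets assume equal spread in every library and no divergence between siRNAs of 1 target. With 200 changed genes the Benjamini-Hochberg cut is also looser than where few genes pass, so recovery in such contrasts can be lower. Contrasts against control share the 3 control libraries, so 100 sets of unchanged groups against common controls were simulated for values that compare such contrasts. All simulated genes varied independently of each other, so the simulated ranges can be too narrow.

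The alternatives set at the same time were quantile normalisation, no filter, a filter at 9 libraries, a pseudocount of 0.1, no cell line block, 4 reagent levels, each PTPN14 siRNA alone, the compared groups alone, each line left out, each library left out, and other thresholds. Median-ratio scaling, further left-out libraries and a correction for GC content and transcript length were added later. Each list reported below as higher or lower kept the sign of its median under median-ratio scaling and quantile normalisation, except ribosomal protein genes with PTPN14-1 against control; some medians near 0 of lists that did not pass changed sign too. Alternatives that need counts were not run. Gene locations and 3′ untranslated regions came from the GENCODE release 29 annotation of GRCh38. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.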

Results

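Transcript levels were measured by polyA RNA-seq 48 h after siRNA transfection of 3 established kidney lines. CAKI-1 and A704 are renal cancer lines and HK2 is an immortalised line from normal kidney. The study's title concerns Hippo signalling in mucinous tubular and spindle cell carcinoma, a kidney tumour, and the siRNAs were aimed at negative regulators of the pathway. LATS1 and LATS2 are its kinases and phosphorylate the coactivators YAP1 and WWTR1 (TAZ). PTPN14 is a non-receptor tyrosine phosphatase that binds YAP1. Each line gave 1 library with a control siRNA, 1 with the LATS siRNA and 1 with each of 2 PTPN14 siRNAs, called PTPN14-1 and PTPN14-2, which makes 12 libraries. Effective depth ran from 17.0 to 23.3 M reads, and 10862 to 11082 genes per library lay above FPKM 1.

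The targeted transcripts were measured first. PTPN14 (chromosome 1, 214348696 to 214552449, minus strand, GRCh38) fell in all 6 PTPN14 libraries. With PTPN14-1 it stood at 21.4% of the control FPKM of the same line in A704, 25.2% in CAKI-1 and 28.7% in HK2. With PTPN14-2 it stood at 37.3, 31.2 and 37.5%. Over both siRNAs the log2 change was -1.62 (SE 0.15, n = 6 libraries against 3, limma adjusted p = 0.00155). The transcript was lower with PTPN14-1 than with PTPN14-2 by a log2 difference of -0.44 (SE 0.11, adjusted p = 0.0213), a call that ended without either A704 PTPN14 library, without HK2 PTPN14-2 or without CAKI-1 PTPN14-1, with adjusted p up to 0.0980.

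With the LATS siRNA, LATS1 (chromosome 6, 149658153 to 149718256, minus strand) fell to 30.7% of control in A704, 27.9% in HK2 and 22.5% in CAKI-1. Its log2 change was -1.36 (SE 0.12, n = 3 against 3, limma adjusted p = 0.00137). LATS2 (chromosome 13, 20973032 to 21061547, minus strand) stood at 110, 98.2 and 122% of control in the same libraries, with a log2 change of 0.12 (SE 0.15, adjusted p = 0.880). The coactivator transcripts did not pass in the target model: YAP1 had a log2 change of -0.04 (SE 0.08) with PTPN14 siRNA and -0.16 (SE 0.09) with LATS siRNA, and WWTR1 had 0.33 (SE 0.10) and -0.06 (SE 0.12).

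**Figure D1:**
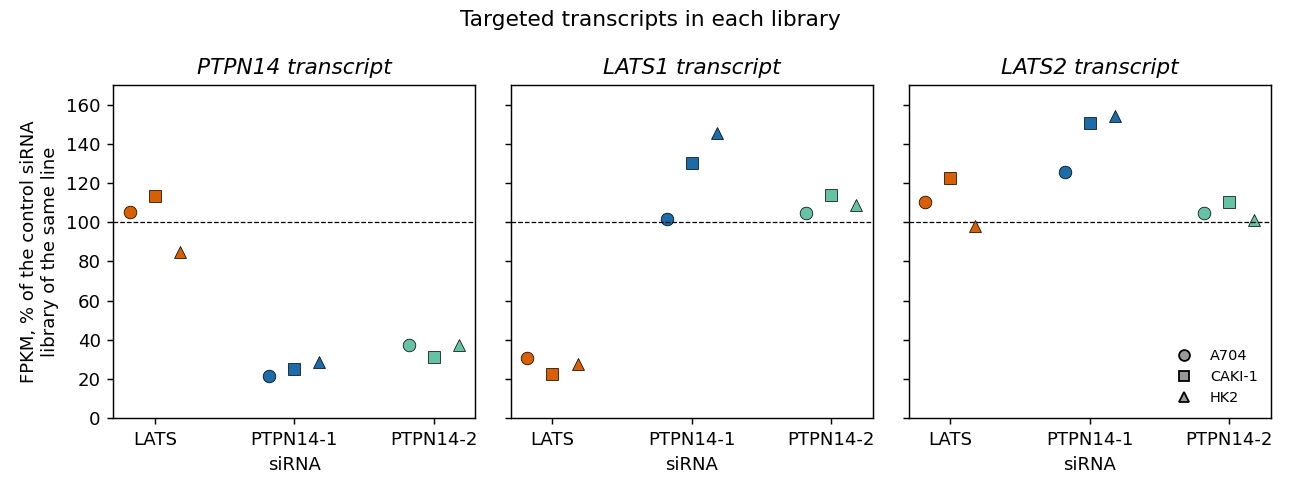
FPKM of PTPN14, LATS1 and LATS2 in each siRNA library as a percentage of the control library of the same line (dashed line, 100%); each point is 1 library, its shape the cell line and its colour the siRNA. PTPN14 lies between 21.4 and 37.5% in the 6 PTPN14 libraries and LATS1 between 22.5 and 30.7% in the 3 LATS libraries, while LATS2 stays between 98.2 and 122% with the LATS siRNA.

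The first comparison asks what PTPN14 siRNA changed in all 3 lines. TSPAN2, which encodes a tetraspanin membrane protein, rose with both siRNAs in every line (log2 change 1.13, SE 0.15, n = 6 against 3, limma adjusted p = 0.0383). In CAKI-1 its FPKM was 2.28 with control siRNA, 11.0 with PTPN14-1 and 7.71 with PTPN14-2, and in A704 it was 1.73, 4.90 and 4.44. FAM174A, which encodes a single-pass membrane protein, fell in every line (-0.93, SE 0.13, adjusted p = 0.0383). In HK2 its FPKM went from 4.58 to 1.43 with PTPN14-1 and 1.13 with PTPN14-2. These genes and PTPN14 were all that passed among 12276, 1 higher and 2 lower, with 1250 genes at an unadjusted p under 0.05. TSPAN2 lies on chromosome 1 at 115048011 to 115089500 and FAM174A on chromosome 5 at 100535305 to 100586741. The count depends on how the siRNAs enter the model: with 4 reagent levels, where their divergence is no longer part of the spread, 149 genes passed (75 higher, 74 lower). That setting tests the mean of the 2 siRNAs, so a gene moved by only 1 of them can pass. With each siRNA tested alone, 26 genes passed with both in 1 direction. TSPAN2 did not pass without any 1 of the LATS libraries, A704 or CAKI-1 PTPN14-2, HK2 PTPN14-1 or the A704 or CAKI-1 control (adjusted p up to 0.326), and FAM174A passed only without A704 PTPN14-1, HK2 PTPN14-2 or the A704 control (up to 0.389 otherwise). The count was 1 without any 1 of the LATS libraries, A704 PTPN14-2, HK2 PTPN14-1, CAKI-1 PTPN14-2 or the CAKI-1 control, 7 without A704 PTPN14-1 and 0 without any 1 line.

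Genes of cholesterol synthesis lay higher as a group with PTPN14 siRNA: 22 of 25 measured members had higher estimates, with a median log2 change of 0.23. INSIG1, a sterol-regulated inhibitor of SREBP processing, was at 0.51 (SE 0.09), SQLE, the squalene epoxidase, at 0.39 (SE 0.09), and DHCR7, an enzyme of the same pathway, at 0.33. None of the 25 passed over all genes, by limma, and 11 did when adjusted over the list alone. The list passed by camera (adjusted p = 8.77e-11) and by fry (adjusted p = 0.0348), but not with an estimated correlation (adjusted p = 0.326). Known YAP/TAZ targets also lay higher by camera (adjusted p = 3.61e-04, 20 of 27 higher, median 0.16). They did not pass with an estimated correlation (adjusted p = 0.627) or by fry (adjusted p = 0.370). Here 0 passed over all genes and 2 when adjusted over the list alone, CRIM1 at 0.60 (SE 0.10) and MYOF at 0.28 (SE 0.07); AJUBA was at 0.46 and AXL at 0.36.

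Another 6 lists passed by camera with PTPN14 siRNA at its preset correlation, and none of them with an estimated correlation (adjusted p from 0.627 to 0.785). By fry none of these 6 passed either (adjusted p from 0.370 to 0.739). A conserved YAP signature passed upward by camera (adjusted p = 0.00630, 40 of 58 higher, 3 past the threshold when adjusted over the list alone, among them CRIM1, DDAH1 and DAB2), as did Hippo components (0.0452, 21 of 32; WWC1 at 0.37 passed over the list alone). Feedback genes of MAPK and EGFR signalling lay lower (adjusted p = 0.00290, 7 of 24 higher; adjusted p = 0.627 with an estimated correlation). EGR1, an immediate early transcription factor, had -0.62 (SE 0.13), PHLDA1 -0.49 and DUSP6, an ERK phosphatase, -0.51, and these 3 passed when adjusted over the list alone. Genes of DNA replication lay lower (0.00104, 4 of 41 higher, median -0.08), and interferon response genes (0.00630, 39 of 44, median 0.16) and actin and adhesion genes (0.0258, 24 of 34) higher, with 0 passing over each list alone. Their adjusted p were 0.661, 0.785 and 0.738 with an estimated correlation. The interferon call ended without the A704 control (adjusted p = 0.918), where its direction turned downward, or A704 PTPN14-1 (0.644), and the Hippo component, actin, replication and MAPK calls each ended without 1 or more single libraries, with adjusted p up to 0.132: A704 LATS, HK2 PTPN14-1 and the CAKI-1 control for Hippo components, the 3 PTPN14-1 libraries and the CAKI-1 control for actin genes, the CAKI-1 control for replication and A704 PTPN14-2 for MAPK genes. The remaining lists had camera adjusted p from 0.0824 (mitosis) to 0.878 (NF-kB), with 0.446 for proximal tubule, 0.359 for loop and collecting duct and 0.162 for podocyte markers.

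The second comparison asks whether the 2 PTPN14 siRNAs did the same. They differed at 1437 of 12276 genes, 678 higher and 759 lower with PTPN14-1 (limma, n = 3 against 3). ETS1, a transcription factor, rose by 0.67 (SE 0.12) with PTPN14-1 and fell by 1.10 (SE 0.12) with PTPN14-2. RMND5A, part of a ubiquitin ligase, fell by 1.14 (SE 0.09) with PTPN14-1 and had 0.28 with PTPN14-2. SLC2A3, a glucose transporter, was higher with PTPN14-1 by 1.17 (SE 0.08, adjusted p = 1.49e-05), and HPRT1, an enzyme of purine salvage often used as a reference gene, by 1.11 (SE 0.08, adjusted p = 1.54e-05). GOLT1B and AP3M1, of vesicle traffic, were also higher with PTPN14-1, by 1.16 and 1.09. OSTC, SLC25A15, ARHGAP19 and FNDC3A were lower, by log2 differences of -1.03, -1.09, -0.97 and -1.25. Each of these 10 differences passed in all 12 fits that left out 1 library. The count was 839 without A704 PTPN14-2, 833 without HK2 PTPN14-2, 876 without HK2 PTPN14-1, 742 without CAKI-1 PTPN14-2, and 503, 319 and 566 without CAKI-1, HK2 and A704.

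**Figure D2:**
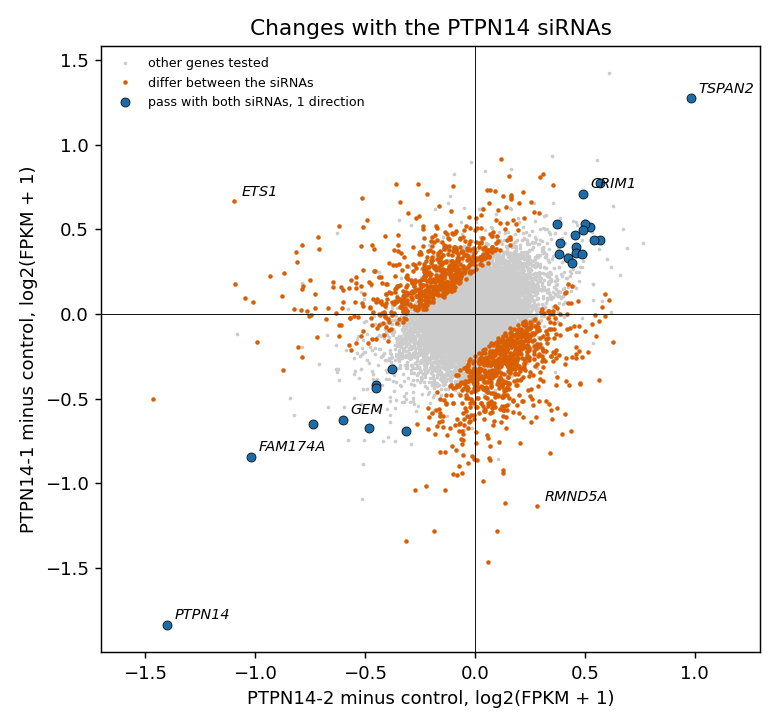
Log2 change against control for each of 12276 genes with PTPN14-2 (horizontal) and PTPN14-1 (vertical), from the model with 4 reagent levels; orange points are the 1437 genes that differ between the siRNAs and blue points the 26 that pass with both in 1 direction. PTPN14 is farthest to the lower left, TSPAN2 to the upper right, and ETS1 lies in the upper left quadrant.

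Against control, PTPN14-1 changed 720 genes (294 higher, 426 lower) and PTPN14-2 changed 166 (55 higher, 111 lower). More genes fell than rose with either. The strongest falls with PTPN14-1 after PTPN14 itself (-1.84, SE 0.11) were SUMF1, which activates sulfatases, at -1.47 and OSTC, part of the oligosaccharyltransferase complex, at -1.34. With PTPN14-2 they were the linker histone gene H1FX at -1.46, PTPN14 at -1.40, ETS1, whose fall is given above, and CD99, a surface glycoprotein, at -1.09. PTPN14-1 also raised CAV1, the main protein of caveolae, by 0.81 (SE 0.09) and DKK3, a secreted protein of the Dickkopf family, by 0.83 (SE 0.09). LATS2 rose with PTPN14-1 (0.47, SE 0.09, adjusted p = 0.00903) and had 0.07 with PTPN14-2, a difference that passed (0.40, SE 0.09, adjusted p = 0.0112) but not without HK2 PTPN14-1 or HK2 PTPN14-2, at adjusted p up to 0.0565. The PTPN14-1 count was 332, 200 and 268 without the A704, HK2 and CAKI-1 control and 241 without HK2 PTPN14-1. The PTPN14-2 count was 92, 43 and 34 without these controls, 84, 66 and 44 without the PTPN14-2 library of A704, HK2 and CAKI-1, and 252 without A704 PTPN14-1.

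YAP/TAZ targets separated the siRNAs. With PTPN14-1, 9 of 27 rose and none fell, and 15 rose when adjusted over the list alone (camera adjusted p = 9.68e-08, fry 0.00865; adjusted p = 0.196 with an estimated correlation). NUAK2, a kinase of the AMPK family, rose by 0.91 (SE 0.11), AMOTL2, an angiomotin that binds YAP1, by 0.70 (SE 0.09), CRIM1 by 0.71 (SE 0.10) and the receptor kinase AXL by 0.56 (SE 0.08). CYR61 and CTGF, secreted matricellular proteins commonly used to report YAP activity and named here after their values were seen, rose by 0.68 (SE 0.12) and 0.45 (SE 0.10). With PTPN14-2, CRIM1 alone rose (0.49, SE 0.10), and over the list alone CRIM1 rose and THBS1 fell (-0.62, SE 0.17); the list had a camera adjusted p of 0.341. The direct contrast between the siRNAs gave 9 targets higher with PTPN14-1 and 0 lower over all genes, and 13 higher over the list alone (camera adjusted p = 2.02e-05, fry 0.00865; adjusted p = 0.291 with an estimated correlation). THBS1, thrombospondin 1, led them at 1.14 (SE 0.17). The conserved YAP signature, which shares members with this list, moved both ways: with PTPN14-1, 8 of 58 rose and 2 fell, DUT, a nucleotide hydrolase, at -0.81 (SE 0.07) and CDKN2C, a kinase inhibitor, at -0.38, and 22 rose and 5 fell over the list alone (camera adjusted p = 5.11e-04, fry 0.0251; adjusted p = 0.307 with an estimated correlation). With PTPN14-2, 2 rose and 1 fell, and 6 rose and 3 fell over the list alone (camera adjusted p = 0.284). Between the siRNAs 14 were higher and 6 lower, and 20 and 7 over the list alone (camera adjusted p = 0.0393, fry 0.0451; adjusted p = 0.585 with an estimated correlation), a call that ended without CAKI-1 PTPN14-1 (0.183).

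Other lists set the siRNAs apart as well. Higher with PTPN14-1 were 9 of 34 actin and adhesion genes, such as ZYX (0.76, SE 0.11) and ACTN1 (0.61, SE 0.09), 9 of 24 MAPK feedback genes, such as DUSP5 (0.83, SE 0.11), 6 of 24 NF-kB genes, such as TNFAIP3 (0.72, SE 0.13), and 11 of 58 ribosomal protein genes, such as RPL38 (0.37, SE 0.07), whose reads can be shared with pseudogene copies. The ribosomal median was 0.19, and 0.07 after quantile normalisation. Against control the ribosomal list passed upward with PTPN14-1 (camera adjusted p = 0.0227; adjusted p = 0.888 with an estimated correlation), but its median went from 0.08 to -0.03 after quantile normalisation, and the call ended without A704 or CAKI-1 PTPN14-1 or the HK2 or CAKI-1 control (up to 0.164). The interferon list had 4 of 44 higher, IFIT1, DDX58, ISG15 and IFIT3, and the replication list 6 of 41 lower, E2F8 the most at -0.85 (SE 0.13). In the actin list 1 member, ACTA2, was lower (-0.47, SE 0.13). Adjusted over the list alone these counts were 13 (and 2 lower), 10, 9, 19, 4 and 7. Camera adjusted p ran from 2.06e-08 for the ribosomal list to 0.00404 for the replication list, and from 0.585 to 0.749 with an estimated correlation. The interferon call ended without A704 PTPN14-1 (0.574) or A704 PTPN14-2 (0.127), and the replication call without HK2 PTPN14-1 (0.136). Another 4 lists passed by camera between the siRNAs, none with an estimated correlation or by fry. Genes of the unfolded protein and integrated stress response were higher with PTPN14-1 (camera adjusted p = 0.00210; adjusted p = 0.585 with an estimated correlation): 7 of 27 were higher, such as ATF3 (0.59, SE 0.12), and 1, CALR, lower (-0.83, SE 0.13), the same counts over the list alone. Genes of mitosis were lower (0.00210; adjusted p = 0.702 with an estimated correlation), with 2 of 32, HMMR and KIF20A, passing over all genes and over the list alone. Mesenchymal genes were higher (0.0291), with 1 of 19 higher, VIM, and 1 lower, ACTA2, and 4 and 1 over the list alone. So were extracellular matrix genes (0.0435), with 4 of 35 higher and 1 lower, COL8A1 (-0.88, SE 0.10), and 7 and 2 over the list alone; adjusted p = 0.585 for both lists with an estimated correlation. The stress call ended without A704 PTPN14-1 (0.0948), the mitosis call without HK2 PTPN14-1 (0.0679) and the mesenchymal call without HK2 PTPN14-1 (0.172) or CAKI-1 PTPN14-2 (0.131). The matrix call ended without A704 PTPN14-2 (0.107), A704 PTPN14-1 (0.115), HK2 PTPN14-1 (0.164) or CAKI-1 PTPN14-2 (0.126). Cholesterol genes had no common direction of difference between the siRNAs (camera adjusted p = 0.903), though 1 of 25 was higher with PTPN14-1, over all genes and over the list alone. Against control, 8 of 25 rose with PTPN14-1 and 2, INSIG1 and SC5D, with PTPN14-2. Adjusted over the list alone, 11 rose with each and 1 fell with PTPN14-1. Camera adjusted p were 7.55e-06 and 2.41e-08 (fry 0.0331 for both; adjusted p = 0.505 and 0.315 with an estimated correlation).

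The genes that passed with both PTPN14 siRNAs in 1 direction numbered 26, of which 17 rose and 9 fell. Independent lists of these sizes would share 1.32 and 3.85 in the 2 directions. At an unadjusted p under 0.05, 454 genes lay in 1 direction with both and 138 in opposite directions, where independent lists would share 210 and 209. In 100 simulated sets of unchanged groups against common controls, which hold no effects, 128 (103 to 163) lay in 1 direction. Each simulated gene was drawn independently, so this range can be too narrow for genes that vary together. Besides TSPAN2 and CRIM1, the shared rises included YOD1, a deubiquitinase, PRSS23, a serine protease, INSIG1, and PLOD2 and P3H2, which hydroxylate collagen lysines and prolines. The shared falls included FAM174A, GEM, a small GTPase, SLC29A1, a nucleoside transporter, and SLCO4A1, an organic anion transporter. GEM fell by 0.63 (SE 0.10) with PTPN14-1 and by 0.60 (SE 0.10) with PTPN14-2, and PRSS23 rose by 0.77 and 0.57. A further 11 genes, ETS1 and SLC2A3 among them, passed with both in opposite directions, against 2.66 and 1.91 for independent lists in the 2 pairings. The control libraries, 1 per line, cannot be split, so part of the overlap may come from them. The 26 became 17, 5 and 3 without the A704, HK2 and CAKI-1 control, 13, 8 and 5 without the PTPN14-2 library of A704, HK2 and CAKI-1, 12 without HK2 PTPN14-1, 17 without A704 LATS, and 49 without A704 PTPN14-1.

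**Figure D3:**
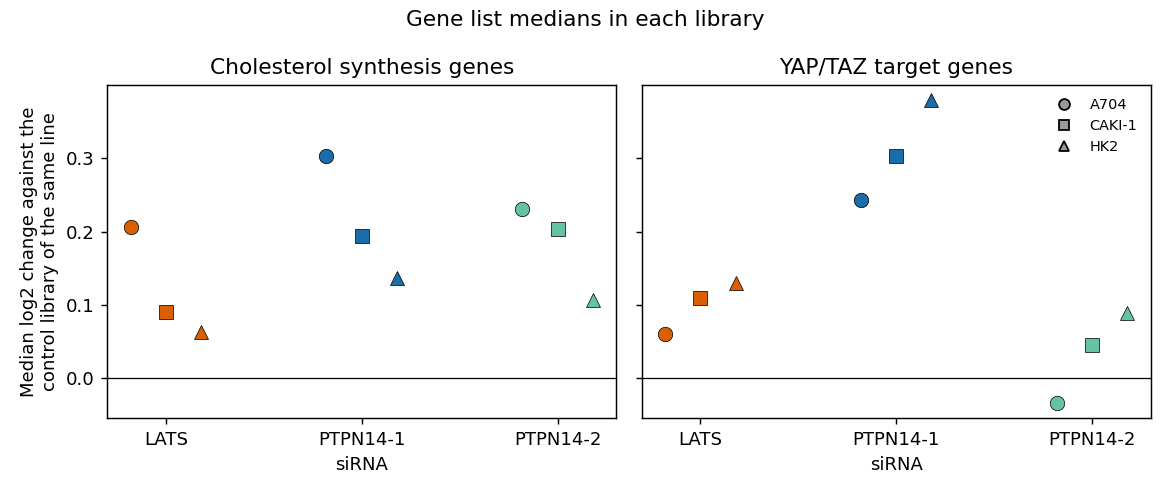
Median log2 change of 25 cholesterol synthesis genes (left) and 27 YAP/TAZ targets (right) in each siRNA library against the control library of the same line; shape is the line, colour the siRNA. The cholesterol medians run from 0.06 to 0.30 and are above 0 in all 9 libraries, while the YAP/TAZ medians are 0.24 to 0.38 with PTPN14-1, -0.03 to 0.09 with PTPN14-2 and 0.06 to 0.13 with LATS siRNA.

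The third comparison asks what the LATS siRNA changed. Beside LATS1, it lowered E2F5, a repressor member of the E2F family, and ACTR1A, a subunit of dynactin, in all 3 lines. E2F5 (chromosome 8, 85177225 to 85217158, plus strand) went from an FPKM of 6.35 to 2.64 in A704, from 6.97 to 3.26 in HK2 and from 11.2 to 4.23 in CAKI-1 (log2 change -1.05, SE 0.11, n = 3 against 3, limma adjusted p = 0.00442). ACTR1A (chromosome 10, 102461881 to 102502711, minus strand) went from 42.4 to 23.3, from 75.4 to 43.4 and from 68.4 to 38.5 (-0.81, SE 0.11, adjusted p = 0.0254). These 3 were all that passed of 12276, each lower, with 888 at an unadjusted p under 0.05; 15 passed with 4 reagent levels (3 higher, 12 lower). E2F5 did not pass without any 1 of the controls (adjusted p up to 0.0731), nor ACTR1A without any 1 of the controls or LATS libraries, HK2 PTPN14-1 or CAKI-1 PTPN14-1 (up to 0.371). The count fell to 1 without any 1 of the controls and to 0 without any 1 line, and was 5 without A704 PTPN14-1.

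With the LATS siRNA 9 lists passed by camera at its preset correlation, and none did with an estimated correlation (adjusted p from 0.627 to 0.661). None of the 9 passed by fry (adjusted p from 0.370 to 0.641). DNA replication genes had lower estimates: none of 41 was higher, with a median of -0.16 (camera adjusted p = 4.78e-09; adjusted p = 0.627 with an estimated correlation). RFC3, a subunit of the clamp loader, was at -0.36 (SE 0.08), MCM4 and MCM3, of the replicative helicase, at -0.23 and -0.24. Genes of mitosis lay lower as well (6.26e-04, 2 of 32 higher; CDK1 at -0.34, TTK at -0.24), as did MAPK feedback genes (0.00630, 6 of 24 higher; PHLDA1 at -0.60, SPRY2 at -0.46). Actin and adhesion genes lay higher (1.92e-06, 29 of 34; MYH9 at 0.29, TPM1 at 0.26), with extracellular matrix genes (6.08e-05, 29 of 35; LOXL2, a lysyl oxidase, at 0.51, SPARC at 0.49) and interferon genes (1.92e-06, 44 of 44; IRF9 at 0.19, OAS3 at 0.40). Cholesterol genes (4.45e-05, 22 of 25; SREBF2 at 0.30), hypoxia genes (6.26e-04, 25 of 30; P4HA1 at 0.29, ENO2 at 0.25) and epithelial genes (0.0370, 18 of 22; ELF3 at 0.37, PAX8 at 0.22) were higher too. By limma 0 members of these 9 lists passed over all genes; when adjusted over the list alone 1 did in the replication list, RFC3, and 1 in the matrix list, LOXL2. Calls ended without the CAKI-1 LATS library for mitosis (0.606), the A704 control for interferon genes (0.0744), the HK2 control for hypoxia genes (0.115), the HK2 LATS library for MAPK genes (0.104), and the A704 or HK2 LATS library or CAKI-1 control for epithelial genes (up to 0.0654). The remaining lists had adjusted p from 0.0605 (podocyte markers and mesenchymal genes) to 0.983 (NF-kB), with 0.268 for proximal tubule and 0.921 for loop and collecting duct markers.

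YAP/TAZ targets did not pass with the LATS siRNA. Of 27, 17 had higher estimates, with a median of 0.10 (camera adjusted p = 0.118), and none passed over all genes or over the list alone; MYOF was at 0.23 (SE 0.08) and AXL at 0.29 (SE 0.14). The conserved YAP signature had adjusted p = 0.546, and its 2 members that passed over the list alone were lower, SHCBP1 at -0.46 (SE 0.10) and MDFIC at -0.48 (SE 0.11). Markers of mucinous tubular and spindle cell carcinoma and other renal tumours did not pass as a list with PTPN14 (15 measured, median -0.01, above 0 after quantile normalisation, camera direction upward, adjusted p = 0.800) or LATS siRNA (median 0.05, adjusted p = 0.385). Between the PTPN14 siRNAs, KRT7 and VIM were higher with PTPN14-1 and CD24 and IRX5 lower, which is 2 and 2 of 15 over all genes and 2 and 3 over the list alone (fry for mixed directions, adjusted p = 5.53e-04; camera adjusted p = 0.976). Markers of leukocytes and of fibroblasts and pericytes, 4 measured in each list, had adjusted p of 0.385 and 0.370 with PTPN14 and 0.432 and 0.119 with LATS siRNA, and only 1 of 12 endothelial markers was measured.

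The fourth comparison sets PTPN14 siRNA against LATS siRNA directly, where the control libraries cancel. It gave 43 genes, 28 higher and 15 lower with PTPN14 siRNA (limma, n = 6 against 3). The targets led, with LATS1 at 1.55 (SE 0.11, adjusted p = 6.47e-05) and PTPN14 at -1.62 (SE 0.15, adjusted p = 3.07e-04). E2F5 was higher with PTPN14 siRNA by 1.27 (SE 0.10), NCEH1, a neutral cholesterol ester hydrolase, by 1.17 (SE 0.10) and ACTR1A by 1.04 (SE 0.09). RRM2B, a ribonucleotide reductase subunit induced by p53, was higher by 0.62 (SE 0.10), and ANKRD13A, C5orf15, TVP23B, POLR3G and PPIC by 0.58 to 0.70. TTYH3, a chloride channel family member, was at -1.04 (SE 0.13), ZNF395 at -0.88, FAM174A at -0.76 and TNS2, a focal adhesion protein, at -0.62; LYRM9, FAM117A, AES, MEIS3 and MAP3K12 lay between -0.70 and -0.54. LATS1, PTPN14, E2F5, NCEH1 and ACTR1A passed in all 12 fits that left out 1 library. The other genes named here each lost their call without 1 or more LATS libraries, and some without others, with adjusted p up to 0.368. Hypoxia genes lay lower with PTPN14 than with LATS siRNA (camera adjusted p = 0.0177, 7 of 30 higher; ENO2 at -0.34, SE 0.08), as did extracellular matrix genes (0.0463, 9 of 35 higher; LOXL2 at -0.34, SE 0.07). By limma 0 members of either list passed over all genes and 1 of each when adjusted over the list alone, and with an estimated correlation the adjusted p were 0.627 and 0.661. Cholesterol genes did not pass as a list (camera adjusted p = 0.0905, 16 of 25 higher, median 0.05), but did by fry for mixed directions (adjusted p = 0.00132), with 0 passing over all genes and 5 higher over the list alone. The count was 5 to 16 without 1 LATS library (7 without A704, 16 without HK2, 5 without CAKI-1), 15 to 27 without 1 other library except HK2 PTPN14-2 and A704 PTPN14-1 (23, 21 and 15 without the A704, HK2 and CAKI-1 controls, 27 without A704 PTPN14-2, 15 without HK2 PTPN14-1 or either CAKI-1 PTPN14 library), 71 without A704 PTPN14-1, and 537 with 4 reagent levels. The hypoxia call ended without the HK2 LATS library (0.122) and the matrix call without the A704 or CAKI-1 LATS library, either CAKI-1 PTPN14 library or the PTPN14-2 library of A704 or HK2 (up to 0.139).

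Across the 12276 genes, which are not independent replicates, the PTPN14 and LATS changes had a Pearson r of 0.302 (jackknife SE 0.237 over libraries). Unchanged groups simulated against the same controls gave 0.578 (0.559 to 0.599 over 100 sets). The covariance was 0.00606 against 0.00539 in the simulated sets (0.00505 to 0.00577). For PTPN14-1 and PTPN14-2 the observed r was 0.211 and the simulated 0.501, with covariances of 0.00685 and 0.00540. In single libraries, changes against the own control correlated across lines at a mean of 0.37 for PTPN14-1, 0.41 for PTPN14-2 and 0.24 for LATS siRNA. Between PTPN14-1 and PTPN14-2 in different lines, which share no control, the mean was 0.04, as it was between LATS and PTPN14 siRNAs in different lines.

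**Figure D4:**
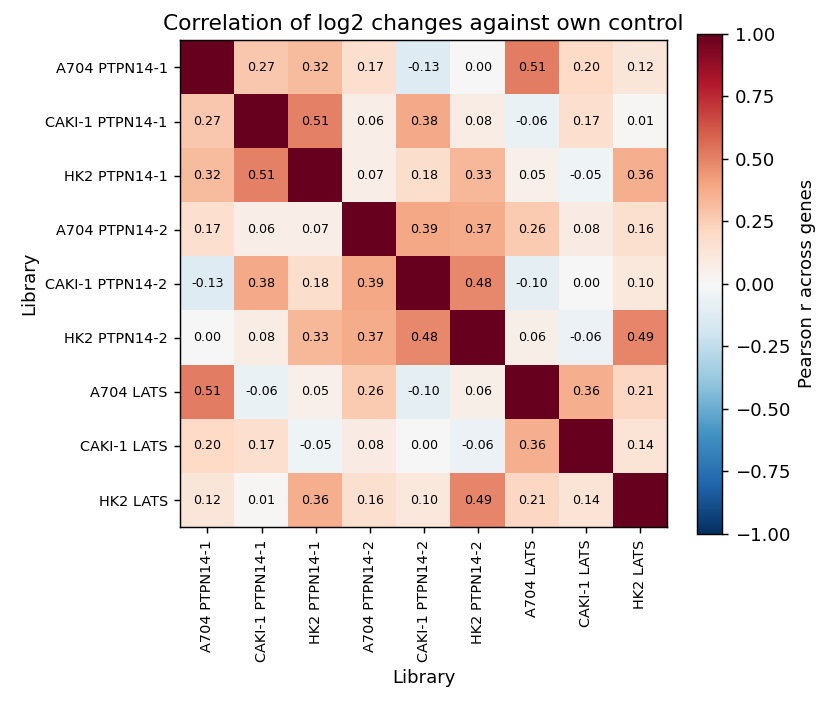
Pearson r, across genes, of log2 changes against the own control for each pair of the 9 siRNA libraries; pairs within a line share their control library. The 3 PTPN14-1 libraries correlate with each other at 0.27 to 0.51 and the 3 PTPN14-2 libraries at 0.37 to 0.48.

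Responses were next compared between lines. In the model of line and target groups no gene passed for PTPN14 or LATS siRNA within A704, CAKI-1 or HK2, by limma, with 206 to 438 genes at an unadjusted p under 0.05. The interaction of line and target also gave 0 genes, with 119 at an unadjusted p under 0.05. All of these unadjusted counts lie below a 0.05 share of the 12276 genes, the share that unchanged genes would give. In this model the spread comes from the pairs of PTPN14 siRNAs, whose changes differ, and PTPN14 itself did not pass within CAKI-1 at -1.66 (SE 0.31), HK2 at -1.55 or A704 at -1.65. TSPAN2 was at 1.64 (SE 0.23) in CAKI-1, 0.69 in HK2 and 1.05 in A704. These fits therefore cannot show whether the lines respond alike.

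The lines themselves differed at most genes: 9605 between HK2 and CAKI-1, 9531 between A704 and CAKI-1 and 10007 between HK2 and A704 (limma, n = 4 libraries per line). These libraries are repeats of 1 line each, so the counts describe these lines, not normal against cancer tissue. Of 11 proximal tubule markers, 10 were higher and 1 lower in A704 than CAKI-1, and 5 higher and 3 lower in HK2 than CAKI-1. GGT1, a brush border enzyme, was higher in HK2 and, by a log2 difference of 3.87 (SE 0.07), in A704. The exception in A704 was ANPEP, a brush border peptidase, which was lower there by -6.07 and in HK2 by -6.03 (SE 0.16). A704 was the line with most GATM, the first enzyme of creatine synthesis, at 4.85 above CAKI-1. HK2 and A704 exceeded CAKI-1 in the simple keratin gene KRT19 by 6.20 and 4.64 (SE 0.07), and CDH1, which encodes E-cadherin, was higher in A704 than CAKI-1 by 4.10 and lower in HK2 than A704 by -4.21. FN1, the fibronectin gene, was lower in A704 than CAKI-1 by -6.02 and higher in HK2 than A704 by 7.79 (SE 0.12), and TNC showed the same order.

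Hippo genes also differed between the lines, over the 4 libraries of each, 3 of which had LATS or PTPN14 siRNA. Of 32 measured components, 15 were higher and 9 lower in HK2 than CAKI-1, 16 and 8 in A704 than CAKI-1, and 15 and 12 in HK2 than A704. TEAD2, a DNA-binding partner of YAP1, was lower in A704 than CAKI-1 by -3.11 (SE 0.09), and WWTR1 was higher in HK2 by 1.28 (SE 0.10) than in CAKI-1 and by 1.16 than in A704. YAP1 was higher in A704 than in CAKI-1 by 0.79 (SE 0.08). Among YAP/TAZ targets, CYR61 was higher in HK2 than CAKI-1 by 2.84 (SE 0.17), INHBA lower in HK2 and A704 than CAKI-1 by -4.22 and -4.93, and ANKRD1 higher in A704 than CAKI-1 by 2.61 (SE 0.17).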

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

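The tests of knockdown strength, of the shared controls and of the ACTR1A 3′ untranslated region, those after a correction for GC content and length, and the count of splits that keep 1 library per line were chosen only after the result was seen.

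PTPN14-1 and PTPN14-2 differed at 1437 genes. Of these genes 19.8% moved in 1 direction with both siRNAs. They were picked for their difference, which favours opposite directions, so this share cannot decide on stronger knockdown by PTPN14-1. Against control, 6 genes passed higher with PTPN14-1 and lower with PTPN14-2, and 5 the other way, which argues against stronger knockdown for those genes. GC content and length are argued against as the whole account, since 1988 genes differed after correction against 1388 of the same 11834 before. They still took up 2.08 to 33.5% of the variance of the changes in single libraries. Off-target binding through 7-base matches in 3′ untranslated regions may contribute: the 7-mer most tied to lower values had a t of -10.86 for PTPN14-1 (GAACGGA) and -15.91 for PTPN14-2 (ACGATGT), the lowest in 100 permutations were -5.44 and -4.93, and the lowest 7-mer in each line was the same or overlapped it. Of genes with an annotated region, 39 of 406 lower with PTPN14-1 hold GAACGGA (9.6%, against 1.6% of those not called) and 31 of 110 lower with PTPN14-2 hold ACGATGT (28.2% against 2.2%). Of the 10 genes named above for this difference, OSTC, lower with PTPN14-1, holds GAACGGA, and GOLT1B and AP3M1, higher with PTPN14-1, hold ACGATGT. ETS1, RMND5A, SLC2A3, HPRT1, SLC25A15, ARHGAP19 and FNDC3A hold neither, but overlapping 7-mers were not looked up in single genes. Among the strongest falls, H1FX holds ACGATGT, while SUMF1 and CD99 hold neither. The PTPN14 transcript holds both 7-mers. Overlapping 7-mers were also tied to lower values, such as AAGAACG for PTPN14-1 (t of -10.6) and CGATGTA for PTPN14-2 (-13.21). Any of the 3 lowest 7-mers of PTPN14-1 stood in 96 of 406 genes lower with it (23.6%, against 5.9% of those not called). For PTPN14-2 this held for 55 of 110 genes, against 13.4% of those not called. The 7-mers were picked on these same values, so the counts describe and do not test, and other differences between the siRNAs stay open. Of 10 splits of the 6 libraries into 3 and 3 the real one gave 1437 and the highest other 0, but 10 splits are too few for a share under 0.05.

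E2F5 and ACTR1A fell with the LATS siRNA beside LATS1. GC content and length are argued against, since both passed after correction, with the higher adjusted p at 0.00341. A 7-mer, ACGAGGA, went with lower values (t = -7.63, lowest permutation -4.68) and was the lowest or overlapped it in 2 of 3 lines, but another 7-mer went with higher values about as strongly (t = 8.2). A different 7-mer, GGATTAC, went with lower values nearly as strongly (t = -7.5). In A704 GGATTAC was the lowest, at -8.74 against -5.2 for ACGAGGA. E2F5 and NCEH1, which also fell with 4 reagent levels, hold ACGAGGA in their 3′ untranslated regions, while ACTR1A holds 0 copies, which argues against a full 7-base match there but not against a shorter one, since it holds the last 6 bases. The LATS1 transcript holds ACGAGGA outside its 3′ untranslated region, and the LATS2 transcript does not hold it. Off-target binding and an effect of LATS1 loss cannot be told apart, since the design has 1 LATS siRNA.

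Cholesterol synthesis genes lay higher with every siRNA than with the control siRNA by camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.326 for PTPN14, 0.627 for LATS, 0.505 for PTPN14-1 and 0.315 for PTPN14-2). GC content and length are argued against, since the PTPN14 median was 0.21 after correction and 0.23 before. The medians were 0.147 with LATS siRNA, 0.196 with PTPN14-1 and 0.202 with PTPN14-2. Between PTPN14 and LATS siRNA, where the controls cancel and low controls can give no difference, 16 of 25 were higher, 0 passed over all genes and 5, all higher, over the list alone (camera adjusted p = 0.0905, fry for mixed directions 0.00132). For the part common to all siRNAs, low values in the 3 control libraries could give this pattern, as could a common response, and the explanations cannot be told apart because each line has 1 control.

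YAP1 estimates with PTPN14 siRNA differed in sign between lines: the mean log2 change was 0.11 in CAKI-1, where both libraries were higher, -0.10 in HK2 and -0.12 in A704, where both were lower, although HK2 PTPN14-1 stood at 99.6% of control. The interaction of line with all targets did not pass for YAP1 (limma adjusted p = 1.00), and this difference was not tested by itself. A search for a library far from the others flagged 0 of 22 groups of values. Each group was a library measure over the 4 libraries of a line or the change of 1 gene over the 6 PTPN14 libraries. Groups this small show only an extreme value, so a library that differs is not excluded.

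Other splits of the libraries were counted for each comparison. The real split is included in each count. For the 3 genes changed by PTPN14 siRNA, 4 of 84 splits gave as many, and for the 43 that differed between PTPN14 and LATS siRNA, 3 of 84 did. Only 27 of the splits keep 1 library of each line in the smaller group, as the real ones do, and all of these splits were among them. The others mix line with group and gave at most 1 and 12 genes, so they say little. Over the 27, 4 and 3 splits gave as many, so chance is not excluded for either count. The highest others gave 1003 and 721, both with the 3 PTPN14-1 libraries set apart, which points to a structure of the siRNAs. Those splits contrast reagents and do not show what chance alone gives. For the 3 genes changed by LATS siRNA the real split gave 3 and the highest other 0 (1 of 10 as large), and 10 splits are too few for a share under 0.05. Between lines, 1 of 35 splits, the real one, gave as many genes (9605, 9531 and 10007, highest other 0). Every other split puts libraries of both lines in each group. Line differences then enter the spread, so these splits cannot decide on chance.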

How the results depend on the processing

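Median-ratio scaling, GC content and length correction, lines left out for the PTPN14 siRNA difference, and libraries left out of the list tests and the tests within lines were chosen after the data were seen. No named gene that passed reversed, and the correlation of the PTPN14 and LATS changes kept its sign. Counts of genes and lists have no sign, so they could not reverse. The interferon list with PTPN14 siRNA turned downward without the A704 control (camera adjusted p = 0.918), and the ribosomal median with PTPN14-1 went from 0.08 to -0.03 after quantile normalisation. Of summary results, 92 of 141 under other settings and 176 of 210 with a library left out stayed the same. These include the interaction and the tests within lines, whose counts of 0 score as the same while they stay at 0. Named genes and passing lists together kept their call in 338 of 514 settings. TSPAN2, FAM174A, E2F5 and ACTR1A kept theirs in 20 of 48 leave-out sets. For PTPN14 siRNA against control (3 genes), quantile normalisation gave 4 (2 higher, 2 lower), no filter 1, a stricter filter 7, GC and length correction 6 (TSPAN2 at adjusted p = 0.0527), 4 reagent levels 149, PTPN14-1 alone 720, PTPN14-2 alone 166, the compared groups alone 1 and adjusted p 0.10 7. Without the cell line block, which pairs the libraries, 0 passed by limma (14 at an unadjusted p under 0.05), and without CAKI-1, HK2 or A704 0, 0 and 0 (730, 561 and 1018 unadjusted); left-out libraries gave 1 to 7. For LATS siRNA (3), quantile normalisation gave 8 (1 higher, 7 lower), a stricter filter 7, 4 levels 15, adjusted p 0.10 9, no block 0 (9 unadjusted) and lines left out 0, 0 and 0 (397, 715 and 542); left-out libraries gave 1 to 5. For PTPN14 against LATS siRNA (43), no filter gave 11, no block 0 (37 unadjusted), 4 levels 537, the compared groups alone 6, a 1.5-fold minimum 15, adjusted p 0.10 166, and lines left out 4, 3 and 6; left-out libraries gave 5 to 71. For the PTPN14 siRNAs (1437), lines left out gave 503, 319 and 566 and left-out libraries 742 to 1638. Within A704, PTPN14 siRNA gave 0 to 1 genes, 1 without PTPN14-2. PTPN14 stayed at -1.62 without the block and at -1.60, -1.65 and -1.60 without CAKI-1, HK2 and A704, and LATS1 at -1.36, and -1.35, -1.31 and -1.43, but none of these passed. Without the block, line differences enter the spread, and without a line there are fewer libraries; for the other moves the cause was not tested. List calls with PTPN14 siRNA (8) were 0 with an estimated correlation (1 unadjusted), 1 by fry and 5 to 9 with libraries left out; with LATS siRNA (9) 0 and 0 (3 and 4 unadjusted); for the difference (2) 0 and 0 (0 and 2 unadjusted), 7 after GC correction, 6 without CAKI-1, 8 without HK2 and 2 to 7 with libraries left out. The correlation of 0.302 moved by less than its jackknife SE (0.209 to 0.508). Alternatives that need counts were not run, changes per line with no test give no count, and a line's control or LATS library cannot be left out of the tests within lines. Depth, 17.0 to 23.3 M reads, is an estimate, so no floor is given for low genes.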

Other observations

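The list tests by single PTPN14 siRNA were chosen only after the data were seen. In the model with 4 reagent levels, TSPAN2 and PSKH1, which encodes a serine kinase, rose with all 3 siRNAs. TSPAN2 was at 1.27 (SE 0.15) with PTPN14-1, 0.98 with PTPN14-2 and 0.94 (limma adjusted p = 0.0358) with LATS siRNA, for which it had adjusted p = 0.200 in the target model. PSKH1 was at 0.44, 0.54 and 0.65. These contrasts share the 3 control libraries, and the genes were chosen after their values were seen. In that model 15 genes passed with LATS siRNA, and NCEH1 (-0.78), TFDP1, a partner of E2F proteins (-0.49), and RCC2 (-0.59) were among the 12 that fell.

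MAPK feedback genes lay lower with PTPN14-2: 1 of 24 had a higher estimate (median -0.24, camera adjusted p = 1.86e-07, fry 0.0331; adjusted p = 0.307 with an estimated correlation). IER3, JUN and PHLDA1 fell, and 5 fell when adjusted over the list alone. With PTPN14-1 the list did not pass (median -0.02, adjusted p = 0.903); DUSP5, FOSL1 and HBEGF rose and EGR1 fell, and 6 rose and 3 fell over the list alone. Ribosomal protein genes also lay lower with PTPN14-2 (5 of 58 higher, median -0.11, camera adjusted p = 7.07e-07; adjusted p = 0.641 with an estimated correlation). With PTPN14-1, 6 of 26 p53 targets rose, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0288, fry 0.0331; adjusted p = 0.380 with an estimated correlation), a call that ended without CAKI-1 PTPN14-1 (0.139) or the CAKI-1 control (0.0794).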
